A study of Drosophila melanogaster with 2 samples.

How the data were processed

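ChIP-seq was performed on whole adult male flies of a line that expresses Clk with a C-terminal green fluorescent protein tag, precipitated with an antibody against the tag, per the labels. The antibody field of the labels names Clk, while the description names the tag. The 2 samples are biological replicates 1 and 2 of 1 group, per the labels. Whether the replicates came from separate fly collections beyond that was not stated. The authors aligned the reads to dm6 and dm3 and compared them with a control alignment, per the file headers of the accompanying notes. The aligner, peak caller, read filters and IDR threshold are not given in the sources used here. Signal tracks and the control data were not used here.

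The authors called candidate regions in each replicate and in both replicates pooled, as peaks and background for the IDR step, and then made the IDR-thresholded list from both replicates, per the file headers of the accompanying notes. The deposited lists are in narrowPeak form. The score used here is the deposited signal value of each region, given by the authors' peak caller on a scale that depends on each library. It was used only to describe and rank regions within a list, and the signal of replicate 1 was 1.70-fold that of replicate 2 over shared regions. The deposited −log10 q-value column was read as such from the format of the lists, and its q-values in the dm6 reproducible list ran from 2.53e-04 to 0.00121, with 80.2% of peaks at the smallest value. For this reason peaks were ranked by score. Summits were taken from the summit offset column. Each dm6 candidate list held 30000 regions, so weak regions beyond that number were not seen. The dm6 reproducible list was the strongest 2464 regions of the pooled list, so the alternative that takes these from the pooled list gives the same peaks by construction. No read counts were used, and depth and its limits on each score are unknown. Exact binomial (Clopper-Pearson) intervals cover counting error over peaks only.

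Coordinates are those of the deposited dm6 lists, written 1-based. Gene annotation was Ensembl release 115 (BDGP6.54) and sequence was the RefSeq Release 6 assembly. No dm6 region ran past the end of a chromosome. Start sites were the 5′ ends of all annotated transcripts. A summit within 500 bp of a start site was called a promoter peak, and other summits were placed in a 5′ UTR, coding exon, 3′ UTR, noncoding exon, intron or intergenic DNA, in an order of precedence. A summit distance of 150 bp counted as shared between replicates.

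The overlap and promoter shares were compared with 1000 random placements on the same arms. The E-box and the 2080 6-mers were counted in windows of 50 bp to each side of the summit and in equal windows centred 400 bp to each side, with the exact McNemar test. The rank test used 100000 resamples. For 20 gene lists fixed before the data were examined, members with a summit within 1 kb of any start site were compared with the other of 13945 protein-coding genes, of which 2248 or 16.1% had one, by Fisher's exact test with Benjamini-Hochberg adjustment at 0.05. Odds ratios and their intervals were computed with a continuity correction added to each cell. All members of the lists matched the annotation. Genes with overlapping or shared promoters can be assigned the same peak.

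The genes named were those nearest to the 20 strongest reproducible peaks with a candidate within 150 bp in each replicate, every clock loop and clock regulator gene, and up to 4 members of each other list with the highest ranked peak within 1 kb. Peaks at Clk, the transgene locus, and on unplaced sequence were to be given with the limit that copy number can affect them. Exceptions chosen after values were seen are stated beside them.

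The overlap, 6-mer, E-box and gene list procedures were tested on simulated data. A simulated overlap of 59.7% was recovered as 60.0%, and independent lists gave 0.446%. With nothing planted no 6-mer was called, and CACGTG planted in 5% of windows gave a gain of 4.87 points. In 49 of 50 simulations an 18-gene list raised to 66% over a background of 15% was called. Alternatives fixed before the data were examined changed the summit distance, number of regions, overlap rule, peak threshold, replicates, windows, control sequence, gene assignment, background genes and matching on start sites; 6 more were added after seeing the data, namely another reference for the replicate overlap, a wider E-box window over all peaks, another E-box window for clock loop and for ribosomal protein gene peaks, dinucleotide shuffles and the histone list without its repeated cluster. No comparison between groups was possible with 1 group. Analyses used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.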

Results

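Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to map where the circadian transcription factor Clock (Clk) was recovered in whole adult male Drosophila melanogaster. The flies carried a transgene for Clk fused at its C-terminus to enhanced green fluorescent protein, and chromatin sheared by sonication was precipitated with an antibody against the fluorescent tag. Clk is a basic helix-loop-helix protein that pairs with Cycle (cyc) and activates period (per), timeless (tim), vrille (vri), Par-domain protein 1 (Pdp1) and clockwork orange (cwo), whose products feed back on the clock. The series held 1 group with 2 biological replicates and no second condition. The comparisons were therefore between replicates, between peaks and the rest of the genome, between summits and their flanking DNA, and between fixed gene lists and all other genes. On build dm6 the authors' list of reproducible peaks, those that passed their irreproducible discovery rate (IDR) threshold, held 2464 regions. Read depth was unknown, because the files gave regions and scores but no read counts. The time of day at collection was not given in the labels.

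The reproducible peaks lay on the major chromosome arms, with 663 on 3R, 533 on 3L, 478 on 2R, 468 on 2L, 318 on X and 4 on chromosome 4. The strongest peak lay in CG11050 on chromosome 2L (6612367 to 6612975, summit 6612710), 1023 bp from the nearest annotated start site, and had the authors' signal value of 1874 against a median of 109 over the list. It ranked first in both replicates. The peak next in strength lay 106 bp upstream of CG14100 (chromosome 3L, summit 19590630, signal 1589), followed by one 31 bp upstream of Ugalt (chromosome X, summit 2703883, signal 1041), a nucleotide sugar transporter gene. The peak at rank 4 lay within Lk6, a gene for a protein kinase that phosphorylates the translation initiation factor eIF4E, in an intron on chromosome 3R (11760864 to 11761262, signal 970). Rank 6 lay inside Trl, which encodes GAGA factor (chromosome 3L, summit 14759502, signal 923), and rank 8 inside Adf1, another transcription factor gene (chromosome 2R, summit 6663049, signal 872). The nearest start sites of the other 14 of the 20 strongest peaks belonged to CG16753, mRpL41, cbt, Tcs5, amon, spen, HmgZ, asRNA:CR45928, Sox14, CG1888, Art3, Tlk, CG31145 and CG3437. The peak assigned to CG16753 lay 5708 bp from that gene's start site, inside CG32486. That assigned to cbt, at rank 9, lay 1347 bp from the cbt start site, inside ush. Those assigned to spen and Tlk lay inside these genes, 7692 and 2341 bp from their start sites. Of these 20 peaks 11 were at promoters, and none ranked below 21 in replicate 1 or below 29 in replicate 2.

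The replicates placed their strongest regions largely at the same sites. Among the clock genes, the tim promoter peak ranked 82 in replicate 1 and 33 in replicate 2, the strongest vri peak ranked 36 and 26, and the per promoter peak ranked 217 and 160. Of replicate 1's strongest 2464 candidate regions, 1702 had a summit within 150 bp of one of replicate 2's strongest 2464, or 69.1% (95% exact binomial interval 67.2 to 70.9). In the other direction the share was 68.8%. Random placement of replicate 2's summits on the same arms gave 0.563% on average and 1.06% at most (one-sided permutation test, p = 0.001, the smallest that 1000 placements can give). The shared regions paired one to one numbered 1668, and across these regions the log2 signal values correlated at Pearson r = 0.845 and Spearman rho = 0.721 (bootstrap interval 0.693 to 0.749). Neighbouring regions are not independent replicates, so no p was attached. The reproducible peaks were the strongest 2464 regions of the pooled list, so the list alone does not show agreement between replicates for each peak. Of these peaks, 88.0% had one of replicate 1's strongest 2464 summits within 150 bp and 79.1% one of replicate 2's. With candidates of any rank, 2398 had a summit within 150 bp in both.

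**Figure D1:**
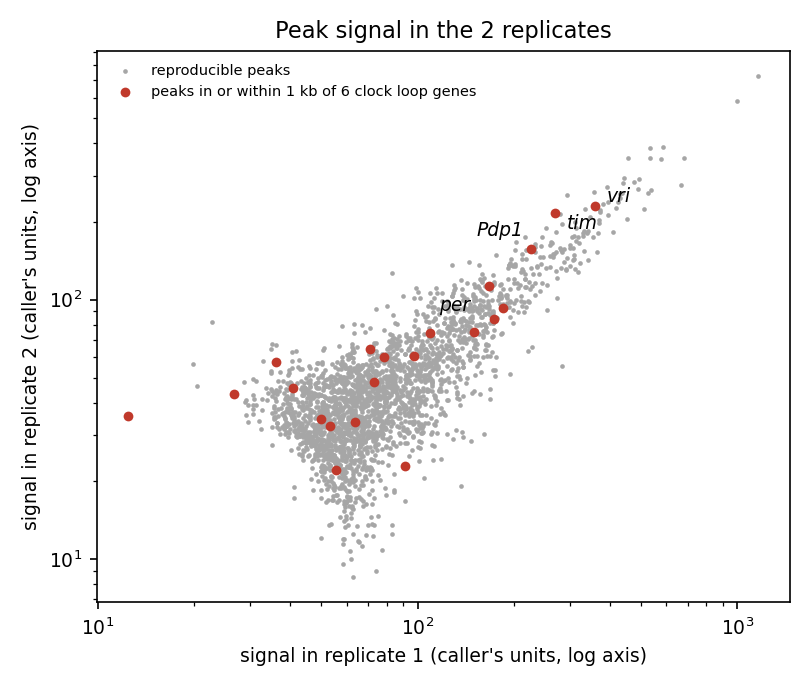
The authors' signal value in replicate 1 (x axis, log scale) and replicate 2 (y axis, log scale) for the 2398 reproducible peaks with a candidate summit in both replicates; red points are peaks in or within 1 kb of the 6 clock loop genes, with the strongest peak of per, tim, vri and Pdp1 named. The strongest vri, tim, Pdp1 and per peaks lie in the upper part of both scales.

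The reproducible peaks were concentrated at promoters. Promoter peaks included those of tim, per, cry, mts and sgg among the clock genes and those of Hsp27, Hsp83 and GstD1 among stress genes. Of 2464 summits, 1584 or 64.3% lay within 500 bp of an annotated transcription start site (95% exact binomial interval 62.4 to 66.2), and the median distance to a start site was 217 bp. Random positions on the same arms gave 13.6% on average and 15.7% at most, a 4.72-fold difference (one-sided permutation test, p = 0.001, the smallest that 1000 placements can give). The weakest 2464 candidate regions of the pooled list had 16.2% at promoters. Introns held 679 summits, or 27.6% (25.8 to 29.4), among them the strongest peaks in Lk6, vri and Pdp1, against 39.3% of random positions. Coding exons held 17 summits, or 0.690% (0.402 to 1.10), against 13.6% of random positions, and intergenic DNA held 125, or 5.07%, against 27.5%.

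**Figure D2:**
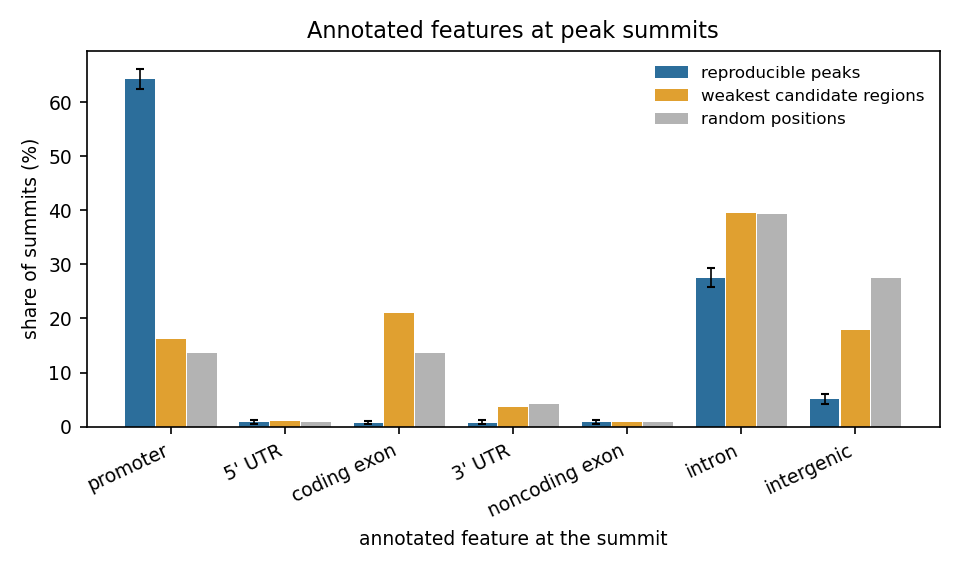
Share of summits in percent (y axis) by annotated feature (x axis) for the reproducible peaks (blue, with 95% exact binomial intervals), the weakest 2464 candidate regions (yellow) and random positions (grey). The blue bar at promoters stands at 64.3%, against 16.2% and 13.7% for the other bars.

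Genes of the core clock loop carried peaks more often than other genes. Of the 6 members, per, tim, vri, Pdp1 and Clk had a reproducible summit within 1 kb of a start site and cwo did not, so that 5 of 6 or 83.3% had one, against 16.1% of the other protein-coding genes (odds ratio 19.1, 95% interval 3.14 to 116, Fisher's exact test, two-sided, Benjamini-Hochberg adjusted over 20 lists p = 0.00376). The list's call was lost when genes were compared only with genes that had a candidate region (5 of 6 against 26.7%, log2 odds ratio 3.33 in place of 4.26, Fisher's exact test, adjusted p = 0.0631) and when lists were matched on the number of annotated start sites (5 genes against 1.51 on average, permutation test, adjusted p = 0.0520). With replicate 2 alone, the cwo start site also had a summit. With the stronger 1232 of the peaks, the Clk start site had none and 4 of 6 genes had one. The tim peak lay on chromosome 2L (3507188 to 3507573, summit 3507368, signal 482, rank 53), at the promoter 150 bp from a start site. The per peak lay on chromosome X (2684896 to 2685228, summit 2685083, signal 281, rank 188), 497 bp upstream of the gene. In vri, which encodes a bZIP repressor of Clk, the strongest of 6 peaks in or within 1 kb of the gene was intronic (chromosome 2L, summit 5301388, signal 584, rank 33). Pdp1, whose bZIP product activates Clk, held 8 peaks, of which the strongest was intronic (chromosome 3L, 7835129 to 7835444, summit 7835292, signal 384, rank 98). The Clk gene held 4 peaks, the strongest in an intron (chromosome 3L, summit 7772365, signal 145, rank 731). Copy number of the transgene can affect signal at Clk, and any part of the transgene that is identical to the endogenous gene maps to the same place. One peak lay within cwo, in an intron (chromosome 3R, summit 10391115, signal 96.1, rank 1534).

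**Figure D3:**
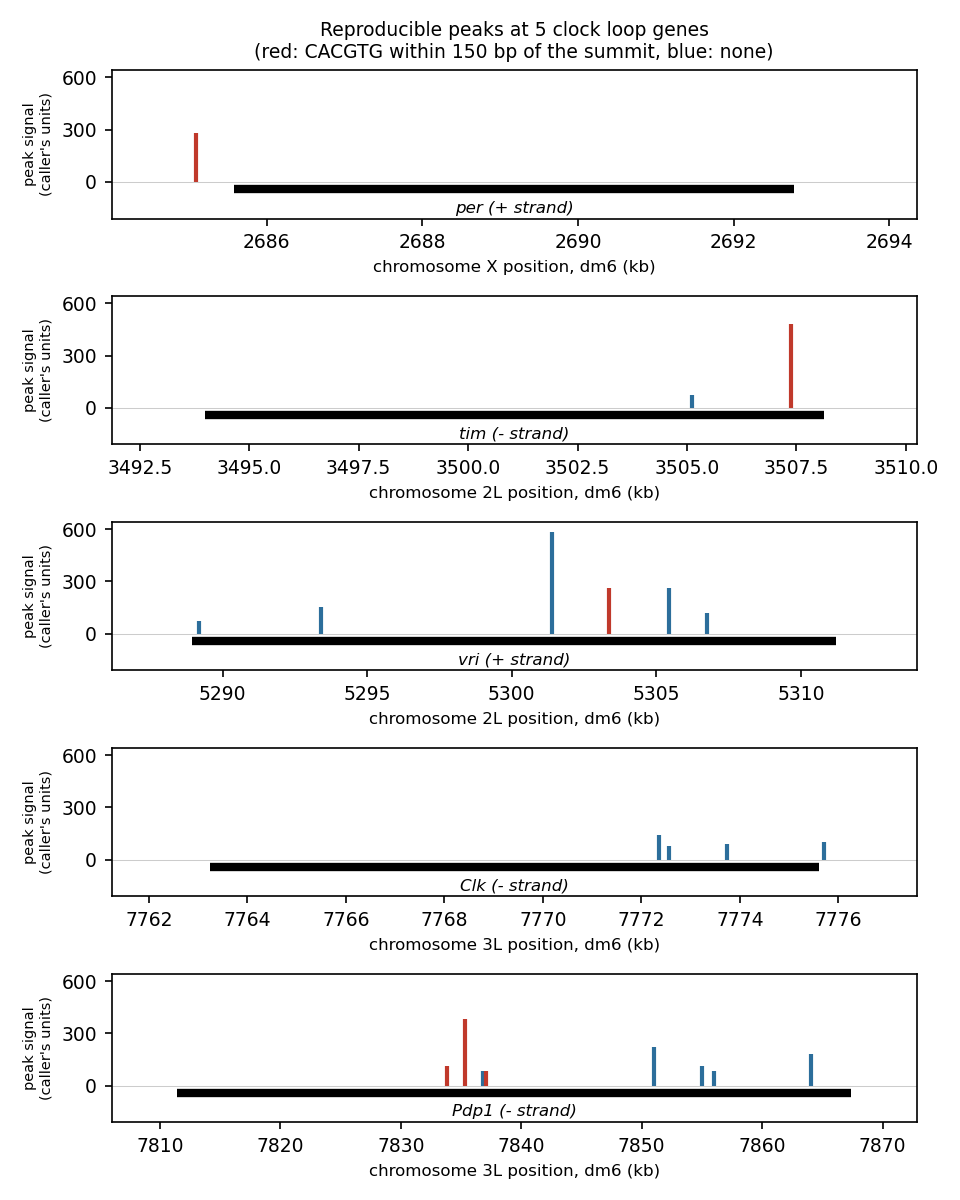
Reproducible peaks at per, tim, vri, Clk and Pdp1 on dm6; each vertical line is a summit with the authors' signal value as its height (y axis) at its chromosome position in kb (x axis), the black bar is the gene, and red lines have CACGTG within 150 bp of the summit. The strongest line is the intronic vri peak at signal 584, and Pdp1 carries 8 lines, 3 of them red.

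Among the 18 further clock regulators, 7 had a peak within 1 kb of a start site, or 38.9% (odds ratio 3.40, 95% interval 1.35 to 8.54), which did not pass the threshold after adjustment (Fisher's exact test, adjusted p = 0.0782). The cryptochrome gene cry, which encodes the blue-light photoreceptor of clock neurons, had the strongest of these, at its promoter on chromosome 3R (summit 19211909, signal 477, rank 54). The others were mts, sgg, tws, wdb, slmb and ctrip, with ranks 407, 572, 772, 1028, 1795 and 2325. With the stronger 1232 of the peaks slmb and ctrip had no such summit, and ctrip had none with replicate 2 alone. The genes mts, tws and wdb encode subunits of protein phosphatase 2A, sgg encodes the kinase that phosphorylates Timeless, and slmb encodes an F-box protein. No reproducible summit lay within 1 kb of a start site of cyc, dco, CkIIalpha, CkIIbeta, jet, nmo, Usp8, Atx2, tyf, Pdfr or kay. Away from the genes' own start sites, peaks lay in or within 1 kb of dco (rank 774), kay (2 peaks, the best at rank 828), nmo (rank 1472) and Usp8 (rank 1726). The Usp8 peak (summit 21138593) lay past the 3′ end of that gene and within 500 bp of a start site of another gene. With replicate 2 alone, kay also had a summit at a start site. With a 5 kb window the count was 13 of 18 (the same exact test, adjusted p = 0.00181), and with each peak given to its nearest start site it was 8 of 18 (adjusted p = 0.00449). With a 500 bp window the count was again 7 of 18 (exact test, adjusted p = 0.0424). Against genes with a candidate region the log2 odds ratio fell from 1.77 to 0.97 (exact test, adjusted p = 0.458), and lists matched on the number of start sites had 4.96 genes with a peak on average (permutation test, adjusted p = 0.600).

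Ribosomal protein genes carried peaks at a high rate. Of 85 such genes 53 had a peak within 1 kb of a start site, or 62.4% against 15.8% of other genes (odds ratio 8.75, 95% interval 5.64 to 13.6, Fisher's exact test, adjusted p = 1.33e-20). The highest ranked were RpS27, RpL14, RpL23A and RpL34b, at ranks 123, 135, 141 and 143 with signals 342, 331, 326 and 325, each with a summit within 107 bp of a start site. Histone genes had peaks less often, at 2 of 115 or 1.74% (odds ratio 0.114, 95% interval 0.0324 to 0.398, Fisher's exact test, adjusted p = 6.57e-06). Of these 115 genes 111 belong to the repeated cluster, and the 2 with a peak, His2Av and His3.3B, were among the 4 outside it, so the lower count rested on the repeated copies. Proteasome genes, another housekeeping group, did not differ from other genes in this test, at 8 of 48 or 16.7% (odds ratio 1.09, 95% interval 0.521 to 2.29). Their highest ranked were Rpn3, Rpn2, Rpn6 and Rpn5, at ranks 937, 956, 1021 and 1023.

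The other 15 lists did not pass the threshold. When each peak was given to its nearest start site, 4 of them beside the insulin list below passed, namely clock outputs with 6 of 16 genes (Fisher's exact test, adjusted p = 0.0361), the bHLH-PAS and Myc family with 5 of 13 (adjusted p = 0.0447), hormone response with 6 of 13 (adjusted p = 0.0128) and immune genes with 6 of 17 (adjusted p = 0.0434). These 4 passed under none of the other alternatives run. Heat shock genes had a peak in 6 of 15 (Fisher's exact test, adjusted p = 0.0782), led by Hsp83, Hsp27, DnaJ-1 and Hsp26 at ranks 190, 197, 295 and 920. Insulin and lipid metabolism genes had one in 8 of 23 (exact test, adjusted p = 0.0782), led by the insulin receptor gene InR at rank 206, the translation inhibitor gene Thor at 527, the lipase gene bmm at 563 and SREBP at 768. In the same exact test, the call for heat shock genes was made with the stronger 1232 of the peaks (6 of 15, adjusted p = 0.00769), with a 5 kb window (11 of 15, adjusted p = 0.00294) and with replicate 2 alone (7 of 15, adjusted p = 0.0227). It was not made with replicate 1 alone (6 of 15, exact test, adjusted p = 0.0782), with a 500 bp window (5 of 15, exact test, adjusted p = 0.198), with nearest start sites (adjusted p = 0.0751), with the candidate background (adjusted p = 0.181) or with matching on start sites (permutation test, adjusted p = 0.112). That for insulin and lipid genes was made with replicate 1 alone (10 of 23, exact test, adjusted p = 0.00874) and with nearest start sites (10 of 23, adjusted p = 0.00167). It was not made with replicate 2 alone (7 of 23, exact test, adjusted p = 0.217), with the stronger 1232 peaks (adjusted p = 0.0650), with a 500 bp window (5 of 23, adjusted p = 0.635), with a 5 kb window (adjusted p = 0.201), with the candidate background (adjusted p = 0.458) or with matching on start sites (permutation test, adjusted p = 0.377). Clock output genes had a peak in 2 of 16, Lk6 at rank 4 and cbt at rank 191. Phototransduction genes had one in 5 of 20, led by rdgC, Rh5, ninaG and rdgB at ranks 234, 467, 656 and 1586. Immune genes had one in 4 of 17, namely imd, cact, PGRP-LB and Rel, and detoxification genes in 3 of 19, namely GstD1, Keap1 and cnc. Of the bHLH-PAS and Myc family 3 of 13 had a peak, gce, tai and sima, and of hormone response genes 2 of 13, EcR and Eip75B. Muscle genes had a peak in 2 of 16, Mef2 and Zasp52, and neuronal genes in 1 of 18, elav at rank 416. No peak lay within 1 kb of a start site of the 18 neuropeptide, 19 testis, 12 accessory gland, 11 fat body or 11 gut genes. For testis genes, the list of these 5 nearest to the threshold, the adjusted p was 0.169, so a lower rate was not detectable with lists of this size.

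**Figure D4:**
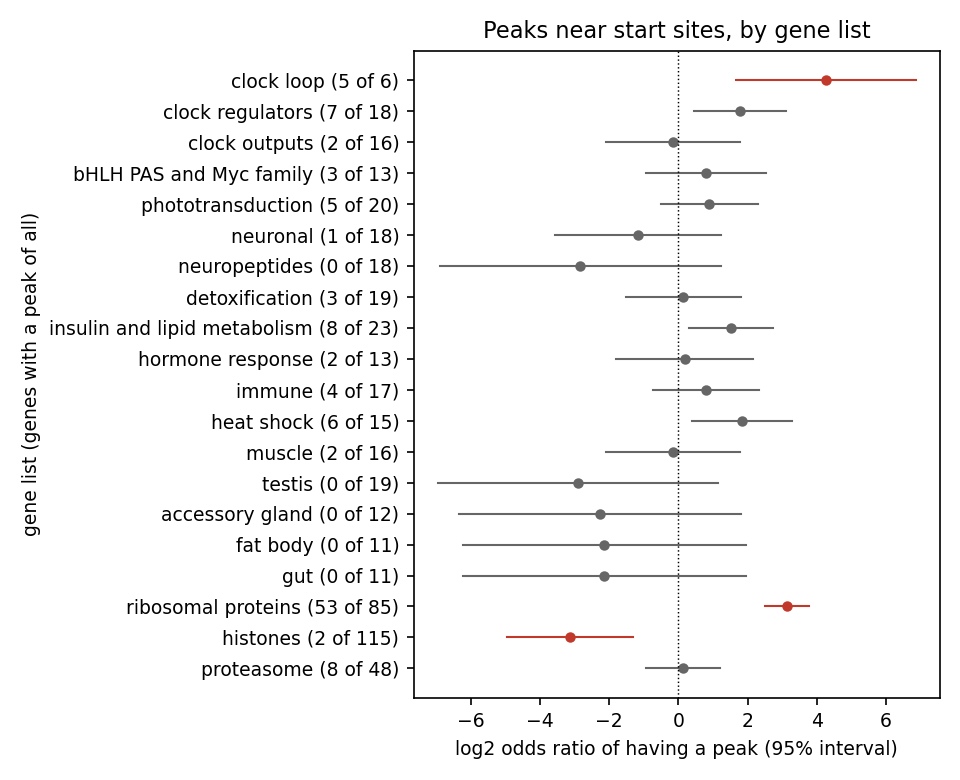
Log2 odds ratio of having a reproducible peak within 1 kb of a start site (x axis, points with 95% intervals) for the 20 gene lists (y axis, with genes having a peak of all genes); red marks the 3 lists with adjusted p under 0.05. The clock loop and ribosomal protein lists lie above 0 and the histone list below.

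The CACGTG E-box, the textbook binding sequence of the Clk and Cycle pair, was present at summits of per, vri and Pdp1 but was not more frequent at summits than beside them over all peaks. Of 2464 peaks, 33 or 1.34% (95% exact binomial interval 0.924 to 1.88) had it in the window that reached 50 bp to each side of the summit. A window of the same width centred 400 bp to the left had 1.22%, a difference of 0.122 percentage points (95% interval -0.510 to 0.753, exact two-sided McNemar test, p = 0.801), and that to the right had 1.06%, a difference of 0.284 points (p = 0.435). In simulated data, CACGTG planted near the centre of 1% of windows at random genomic sites was detected against the left flank in 82 of 100 runs. The planted position was fixed, so this does not measure how well a gain would be seen if summits are imprecise. The sites were also drawn once for all runs. Real summits were poorer in G and C than their flanks (38.7% on average against 43.6% and 42.9%), which random sites do not reproduce. The 82 runs therefore do not give the sensitivity at the peaks. The E-box share did not follow peak strength. In 5 classes from the strongest to the weakest peaks it was 1.42%, 0.811%, 1.83%, 0.609% and 2.03% (Spearman rho of rank and presence 0.0132, permutation test across peaks, two-sided, p = 0.513). None of the 20 strongest peaks had the E-box in that window.

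At per, the E-box lay on chromosome X at 2685050 to 2685055 in AAAGCCGCCGCTCACGTGGCGAACTGCGTG, upstream of the gene, with its centre 30 bp to the left of the summit on the reference strand. In vri it lay in an intron on chromosome 2L at 5303352 to 5303357 in CACATTCCACGACACGTGACCGCTCCGCCG, in a peak of rank 213. Pdp1 had the E-box in 3 intronic peaks of ranks 98, 1172 and 1992, on chromosome 3L at 7835259 to 7835264 (ACGTTTCGCTACCACGTGCACCGGCGGTCT), 7833829 to 7833834 (CACAGTTCTAAGCACGTGTTGCGGACACAC) and 7837080 to 7837085 (GAAGACTATGCGCACGTGTTTCAGCCAAAC). At tim the E-box was 52 bp from the summit, on chromosome 2L at 3507417 to 3507422 in GGGAAATCGGCTCACGTGTAATCACAACGT, and therefore outside the 50 bp counted.

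Other 6-base sequences did differ between summits and flanks. With each 6-mer counted together with its reverse complement, 180 of 2080 were more frequent at summits and 458 less frequent (exact two-sided McNemar test against the flank with the larger share, Benjamini-Hochberg threshold 0.05). The comparison used the higher flank, which favours lower calls, and 212 of the 458 were lower than both flanks. Of the 180 higher 6-mers, 33 had no G or C and 91 had a single G or C. All 458 lower 6-mers had 2 or more G or C. Summit windows were poorer in G and C than the flanks, at 38.7% on average against 43.6% and 42.9%. The flank comparison did not adjust for this, so calls in either direction can reflect base composition. CACGTG has 4 G or C, so the same gap applies to its flank comparison. The largest gain was that of AAATAA, found in 30.4% of summit windows and 18.9% of the flank. TATCGA, part of the element bound by DREF and of sites of the insulator protein BEAF-32, was at 8.69% of summits and 4.02% of the flank (exact McNemar test, adjusted p = 1.61e-09). ACACTG was at 9.74% and 4.63% (exact test, adjusted p = 1.24e-09), and ACAGTG at 9.38% and 4.46% (adjusted p = 7.08e-10). These 3 were named after their values were seen. They were also more frequent than in dinucleotide-preserving shuffles of the same windows, where 150 6-mers were higher and 160 lower, and 45 of the 150 were also higher against the flanks. Against the flanks, no 6-mer of the E-box family examined passed the threshold. Against the shuffles 1 of them did, CAGCTG, at 5.11% and 2.03% (exact McNemar test, adjusted p = 1.08e-07), while CACGTG was at 1.34% and 1.75% (exact McNemar test, adjusted p = 0.531).

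**Figure D5:**
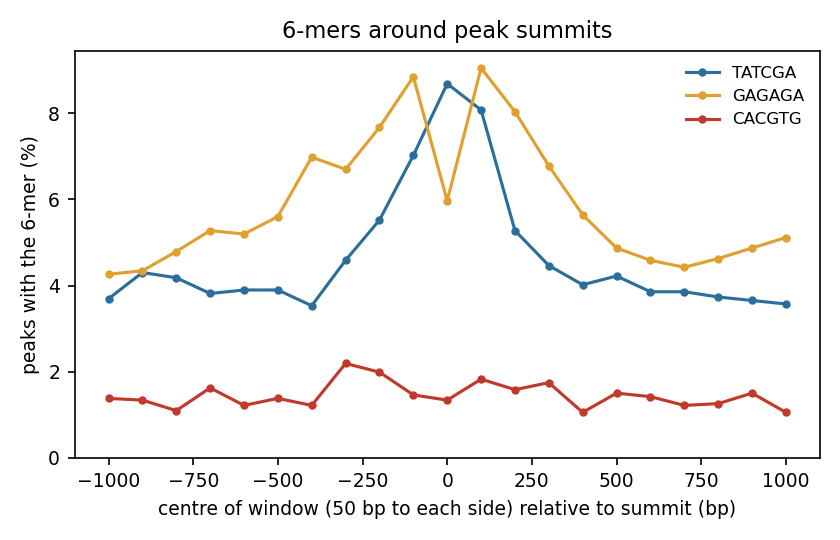
Share of reproducible peaks in percent (y axis) with TATCGA (blue), GAGAGA (yellow) or CACGTG (red) in windows of 50 bp to each side of their centre, by the distance of the window's centre from the summit in bp (x axis). TATCGA is at 8.69% at the summit and 8.08% at 100 bp to the right, GAGAGA is at 5.97% at the summit and 9.05% at 100 bp to the right, and CACGTG stays between 1.06% and 2.19%.

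The authors also gave lists on the older build dm3, and peak numbers were set beside each other without converting coordinates. The reproducible list had 2119 regions on dm3 and 2464 on dm6. The pooled candidate list had 21744 regions on dm3 and 30000 on dm6, and the single-replicate lists had 25384 and 28799 on dm3 against 30000 each on dm6. No test was made, because each count is a single value.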

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

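On dm3, 56 of the 21744 pooled candidate regions lay outside the main arms, on heterochromatic or unplaced sequence. They were flagged because they were left unanalysed. The dm3 build includes such sequence, so regions there are not unusual by themselves. The single-replicate lists had 103 and 133 such regions in replicates 1 and 2. One of the 2119 reproducible dm3 peaks lay there, on unplaced sequence, where copy number can affect signal. These regions were part of the dm3 totals set beside those of dm6 and entered no other comparison. No biological explanation was tested. With groups of 2 samples no sample was tested as an outlier.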

How the results depend on the processing

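The replicate overlap and promoter excess kept their direction and side of the threshold under every alternative run; the overlap ran from 48.8% (50 bp) to 73.7% (any 1 bp overlap), and the promoter share from 53.4% (250 bp) to 74.7% (1 kb). A reference added after seeing the data drew regions from replicate 2's other candidates and gave 2.56%, beside the overlap of 69.1%. These candidates exclude replicate 2's strongest regions, where the matches lay, so a low share was built in. This reference therefore cannot test the overlap, and no conclusion was drawn from it. Spearman rho moved to 0.767 at 50 bp and 0.636 over all candidates. No paired analysis was possible because there was 1 group. The E-box difference turned to -0.0406 points against the weakest candidates, and the rank correlation to -0.0159 in the stronger 1232 peaks and -0.00407 at 51 bp. The count of higher 6-mers moved to 86 at 51 bp. The 3 lists past the threshold became 5 at 5 kb, 9 by nearest start site and 1, ribosomal proteins, against genes with a candidate region. Leaving out a replicate gave promoter shares of 62.3% to 64.7%, E-box differences of 0 to 0.0812 points, rank correlations of 0.00732 to 0.0179, 170 to 176 higher 6-mers and 4 lists each time. E-box differences against flanks under the alternatives were taken from the flank with the closer share, which pulls them toward 0 by construction. They are therefore no independent evidence that an excess is absent. Lists that turned sign, starting from values that did not pass unless named, are given as log2 odds ratios, or, where matched on start sites, as the log2 ratio of genes with a peak to the mean of the matched lists (0.5 added to each): clock outputs (0.75 in the stronger peaks, -0.16 to 0.49 leaving out a replicate, 0.0672 at 500 bp, 0.53 at 5 kb, 2.04 by nearest start site), proteasome (-0.55 to 0.32 leaving out a replicate, -0.26 by nearest start site), muscle (0.0672 at 500 bp, 0.78 by nearest start site), fat body (0.48 at 5 kb), detoxification (odds ratio -0.49 with the candidate background, count ratio -0.0790 matched on start sites), hormone response (-0.75 and -0.85 in the same settings) and histones, which had passed (1.46 with the candidate background, 2.38 without the repeated cluster, 2 of 4 genes). For histones the loss of the repeated genes is the cause by construction; for the rest the cause was not tested. Read depth was unknown, so its limit on weak peaks could not be stated.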

Other observations

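Tests in this part were chosen after the results were seen for the centring of TATCGA, the E-box over all peaks within 150 bp, the 3 named 6-mers at ribosomal protein genes, the E-box at clock loop genes, by peak and by gene, with and without Pdp1 and in both windows, the E-box within 50 bp at ribosomal protein genes, the X chromosome and the tRNA genes with a sequence found once; the matching on start sites was an alternative fixed before the data were examined, but its use to weigh start site number was chosen after its value was seen; the genes named in the next paragraph were also chosen after their values were seen. The tests of tRNA genes, of the E-box at ribosomal protein genes and of the Clk region were set before their values were computed. The Poisson limit given for the Clk region was not part of the test set before.

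Some genes held several reproducible peaks in or within 1 kb of the gene. CHES-1-like, a forkhead gene on chromosome X, had 10, sbb and the overlapping Glut4EF and CG46467 had 9 each and tara had 8. Pdp1 also had 8, and vri, spen, tai, Eip75B, REPTOR and Trl had 6 each. Of 2795 protein-coding genes with any such peak, 39 had 5 or more. Genes on X had a peak within 1 kb of a start site less often than genes on the large autosomes, at 231 of 2196 or 10.5% against 2013 of 11669 or 17.3% (odds ratio 0.565, 95% interval 0.489 to 0.653, Fisher's exact test, p = 2.84e-16). The same comparison gave 11.1% against 17.2% with replicate 1 alone and 9.52% against 16.8% with replicate 2 alone. Pooled candidate regions of any strength were also sparser on X, at 149 per Mb against 234 to 248 on the large autosomal arms. X held 11.7% of these candidates and 12.9% of the reproducible peaks, so the shortfall was not particular to the reproducible peaks. Males carry a single X, and the cause was not tested. Chromosome 4 had 111 candidate regions in replicate 1 and 378 in replicate 2, of which 3 and 7 were among each replicate's strongest 2464. Within 50 bp of the summit, TATCGA was in 28.8% of the 59 peaks within 1 kb of ribosomal protein gene start sites and 8.19% of other peaks (Fisher's exact test, unadjusted p = 4.98e-06), ACACTG in 22.03% and 9.44% (p = 0.00567) and ACAGTG in 11.9% and 9.31% (p = 0.495). Summit windows held 38.7% G and C on average, against 43.6% and 42.9% in the flanks.

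Over all peaks no excess of CACGTG was detected at summits, either within 50 bp or within 150 bp against whichever window 1 kb away had the closer share (difference 0.0812 percentage points, exact McNemar test, p = 0.945), although clock loop genes had peaks. How many of all the peaks depend on the tagged protein is unknown, because no precipitation from untagged flies was analysed here. Imprecise summits stay open as an explanation. TATCGA, picked because it was higher at summits, gained 4.67 points over the higher flank 400 bp away (95% interval 3.31 to 6.02). Its gain was 0.609 points over the window 100 bp to the right (-0.886 to 2.10), the higher of the nearer windows, and 1.66 points over that to the left. A candidate explanation is that the E-box belongs to a small subset of peaks: within 50 bp of the summit it was in 5 of 22 peaks in or within 1 kb of clock loop genes, or 22.7%, and in 28 of 2442 others, or 1.15% (odds ratio 26.6), but the 5 lay in per, vri and Pdp1 alone and peaks of one gene are not independent. With genes as the unit, 3 of the 6 had it, against 0.499 on average in genes of similar peak number (exact test stratified by peak number, two-sided, p = 0.00792; without Pdp1 2 of 5, p = 0.0352), and within 150 bp 4 had it against 1.09 (p = 0.0101), a test on genes whose E-boxes had been seen and so no independent evidence. Peaks in or near clock regulator and clock output genes had it within 50 bp in 0 of 18 and 0 of 13. With 1.15% of other peaks holding it, 0 in so few peaks gives no contrast. Within 150 bp it was in 6 of the 22 clock loop peaks, or 27.3%, and in 4.46% of the other peaks. In that window 0 of the 18 clock regulator peaks and 3 of the 13 clock output peaks, at cbt and Lk6, had it. The E-box in this window was therefore not particular to clock loop genes.

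Ribosomal protein genes had peaks in 53 of 85. Lists matched on the number of start sites had 17.0 genes with a peak on average (permutation test, adjusted p = 0.00200), which argues against start site number as the whole cause. CACGTG lay within 150 bp of the summit in 8 of 59 peaks at these genes, or 13.6% (95% exact binomial interval 6.04 to 24.98), against 4.45% of other peaks (Fisher's exact test, p = 0.00531), a higher share that still leaves most of these peaks without it; within 50 bp it was in 3 of 59, or 5.08%, against 1.25% (p = 0.0428). Recovery at strongly transcribed genes whatever protein is tagged stays open: 8 of 290 tRNA genes had a summit within 500 bp, or 2.76%, against 14.1% of protein-coding genes (Fisher's exact test, p = 1.48e-10), but many tRNA genes are repeated and of the 52 with a sequence found once on the arms 3 had one, or 5.77% (95% exact binomial interval 1.21 to 15.9), which includes the protein-coding share. A precipitation from untagged flies was not analysed here.

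Clk and its neighbour Pdp1 on 3L held 4 and 8 peaks, and extra copies of the region in the transgenic flies are a candidate explanation. Some of these peaks overlapped, at Clk 7772155 to 7772574 and 7772354 to 7772773. At Pdp1, which is 55.9 kb long, 7836613 to 7837032 and 7836878 to 7837297 overlapped. Such counts were not rare, as 73 protein-coding genes held 4 or more peaks. The 35.9 kb between the genes held 18 pooled candidate regions, at the 90.3 percentile of 3262 windows of that size that held any. An equal stretch on the other side of Clk held 5, at the 35.5 percentile. The test set before counted against extra copies if either stretch lay at or below the median window, which held 8 regions. The second stretch met this. Its count has a Poisson upper limit of 11.7, at the 68.6 percentile, which was not part of the test set before. A number of called regions does not measure copy number, and no read counts were used. The extent of the transgene is also not given in the sources used here. For both reasons the explanation could be neither excluded nor borne out. No biological explanation was tested for this pattern.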
